A study of Mus musculus with 12 samples.

How the data were processed

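The deposited files hold 1 matrix per library of whole-number UMI counts for 32285 features and the barcodes that the authors called as cells, and per the file headers these counts were made with Cell Ranger 6.0.0. Per the labels, reads were mapped to mm10 (GRCm38) and Seurat was used downstream; the version of Seurat and the settings of the cell call are not given in the sources used here. The labels name 10x Genomics 3' chemistry v3 and the series design v3.1. The deposited counts are not normalised, and barcodes with few genes or a high mitochondrial share are still present. Gene identifiers were compared with GENCODE M21: 32158 of 32285 matched, 127 did not, and 31436 had the same symbol, and positions are from that annotation. The design has 6 days with 2 libraries each, per the labels biological duplicates. Organoids were begun with 3000 cells per well, with 2% matrigel from DIV1 and 1% matrigel from DIV8. For dissociation the labels name Accutase at DIV3 and DIV4, thermolysin for 20 minutes and then Accutase at DIV8, DIV16 and DIV21, and no enzyme for DIV11.

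Barcodes with at least 500 genes and under 20% mitochondrial UMIs were kept, 103444 of 142109. Doublets were scored with Scrublet, run through scanpy 1.11.5, at an expected rate of 0.008 per 1000 barcodes of the library. Its automatic threshold called under 0.5% of cells in 9 libraries, so the expected number of cells with the highest scores was removed, 12364 in all, a choice made after this was seen. Median UMIs per retained cell ranged from 2174 (DIV8 replicate 2) to 16663 (DIV3 replicate 2). Intervals and floors cover counting error only. For a class at 1 cell in a library the exact 95% interval (Clopper-Pearson) is wide, for example 0.019% to 4.12% for endoderm-like cells in DIV3 replicate 1, and a count of 0 cells allows a share of up to 2.74% in that library.

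Retained cells were clustered together without integration: 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.0 (0.5 and 2.0 as alternatives), seed 1, with scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2 and igraph 0.11.9. A cluster was named after the marker list with the highest score if its score was at least 1.0, lay 0.3 above the next, and enough of its markers were detected in at least 10% of cells with a log2 fold of at least 1.0 over the other clusters (5 CPM added). Its leading genes also had to include a marker of that list and not more markers of other lists, and clusters led by placental genes were left unnamed. Clusters whose UMIs per cell lay below the library median divided by 3 were set apart as low-UMI clusters. These naming settings were chosen after the clusters were seen; the marker lists were not. Otic epithelium-like cluster 31 (3.652, cartilage second at 3.202) was scored on 11 markers, the size of the otic supporting cell list (otic epithelium: 13). Clusters that met no list keep their number, and names are candidates ("-like"), not proof of identity.

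Whole-organoid tests used UMI counts summed over all retained cells of each library, so the library and not the cell is the unit. Counts were filtered with filterByExpr (19664 genes tested), scaled with TMM and fitted with glmQLFit and glmQLFTest in edgeR 4.0.16 (R 4.3.3) with day as a factor over all 12 libraries, and consecutive days were compared. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The standard error of a log2 fold change is its size over the square root of the F statistic. With 2 libraries per group no exact permutation test can reach 0.05, and the fit pools the spread over all days. Within a class the same fit used the cells of that class in libraries with at least 30 of them. Class shares were tested with edgeR on cell numbers with the retained cells as library size, adjusted over all classes and comparisons. Gene lists (41 with at least 5 tested genes) were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, with limma 3.58.1. In the whole-organoid comparisons a list not mentioned had a camera adjusted p of 0.05 or more, and within classes only part of the called lists is given. All genes of the lists are in the files except Aldoa, so 15 of 16 hypoxia and glycolysis genes were used. The lists were written from general knowledge of the cell types, and some genes stand in more than 1 list.

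Named genes follow a rule: the 8 largest rises and 8 largest falls of a whole-organoid comparison (6 and 6 within a class) among genes with an adjusted p under 0.05, a mean of at least 20 CPM over the 4 libraries and both libraries of 1 day above both of the other. Predicted genes, clone-named genes, mitochondrial and ribosomal protein genes, Xist and Y-linked genes were passed over. Up to 4 members of each called list with the smallest adjusted p, and the fixed markers Fbxo2, Atoh1, Pou4f3, Myo7a, Sox2, Pax2, Oc90 and Pou5f1, were added. Not every gene that this rule picks is reported here. A gene with 0 counts at a day has a bound in place of a fold, computed against 3 counts per library. The comparisons, tests, gene lists, naming rule for genes and most alternatives were set before the data were examined.

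The edgeR gene test on summed counts was tried on simulated negative binomial counts with the fitted means and tagwise dispersions and 200 changed genes. Cell filters, doublet removal, clustering, naming, share and list tests were not simulated. Of genes changed 2-fold, 52.04%, 38%, 46.94%, 56.12% and 58% were recovered in the whole-organoid comparisons in order of day, and of genes changed 4-fold 69.7%, 77.08%, 83.51%, 80.81% and 80.85%. Within classes the recovery at 2-fold was 44.21% in otic epithelium-like, 52.69% in hair cell-like, 68.69% and 72.73% in mesenchyme-like and 51.02% and 54.26% in epidermis-like cells, and at 4-fold 93.62%, 91.49%, 88.42%, 95%, 94.74% and 80.61%. Alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, replicate number as a block, leaving out each library, all deposited barcodes, 1000 genes or 10% mitochondrial UMIs as limits, doublets kept, libraries thinned to the smallest total, 100 cells per library for classes, limma on log2 shares and fry for lists. The 4 compared libraries alone were also fitted. Alternatives added after the data were seen are named below. The other tools were python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and the R package data.table, version 1.17.8. Log CPM of the 2 libraries of a day correlated across genes at Pearson's r = 0.9706 (DIV3) to 0.9945 (DIV11), where genes are not independent replicates, and the first principal components of the libraries held 63.45% and 17.89% of the variance and separated the days. Read-level data were not used here.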

Results

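Single-cell RNA sequencing libraries were made from mouse inner ear organoids, aggregates of embryonic stem cells that are steered stepwise toward the tissue that forms the inner ear. The cells carry Fbxo2-VHC, a Venus, hygromycin-resistance and Cre reporter at Fbxo2, a gene of the developing inner ear. The transgene itself is not among the counted features. The 12 libraries cover 6 days in vitro (DIV), which are DIV3, DIV4, DIV8, DIV11, DIV16 and DIV21, with n = 2 biological replicates per day. After quality filters 91080 of 142109 deposited barcodes were retained, from 133 to 13201 per library. Retained UMIs in replicates 1 and 2 were 6094785 and 121325898 at DIV3, 38685156 and 52571339 at DIV4, 83305723 and 88219944 at DIV8, 94887653 and 70982703 at DIV11, 89157361 and 87579093 at DIV16, and 89506204 and 77802888 at DIV21. DIV3 replicate 1 holds only 133 cells. At DIV4 51.1% and 40.6% of the barcodes had at least 20% mitochondrial UMIs and were removed, against 0.522% to 4.83% in the libraries of the other days. Gene levels are CPM, the UMIs of a gene scaled to a common library total over all retained cells, given as mean ± SD of n = 2 libraries. Log2 fold changes carry their standard error. Where 1 to 3 UMIs of a gene were counted at 1 of the days, its UMI totals over both libraries of each day stand in place of a fold change. Every gene called changed here was higher in both libraries of one day than in both of the other. Adjusted p-values come from edgeR unless another tool is named.

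Fixed markers of pluripotency, otic epithelium and hair cells were followed over the days. Pou5f1 (ENSMUSG00000024406, mm10 chromosome 17, 35506018 to 35510772), which holds cells pluripotent, went from 446 ± 255 CPM at DIV3 to 1.04 ± 0.472 at DIV21. Fbxo2 (ENSMUSG00000041556, chromosome 4, 148160621 to 148166424) was lowest at DIV8, at 0.921 ± 0.293 CPM, and reached 76.2 ± 35.4 at DIV21. Oc90 (ENSMUSG00000015001, chromosome 15, 65876053 to 65912397), which encodes the main matrix protein of otoconia, had 0 counts at DIV8, 1.07 ± 0.284 CPM at DIV11 and 76.3 ± 47.9 at DIV21. The hair cell transcription factor genes Atoh1 (ENSMUSG00000073043, chromosome 6, 64729125 to 64731245) and Pou4f3 (ENSMUSG00000024497, chromosome 18, 42394539 to 42397249) reached their highest means at DIV16, at 5.69 ± 2.49 and 8.25 ± 3.30 CPM. Myo7a (ENSMUSG00000030761, chromosome 7, 98051060 to 98119524), a motor protein gene of the hair bundle, stood at 2.04 ± 0.682 CPM at DIV16 and 2.09 ± 0.283 at DIV21. Sox2 (ENSMUSG00000074637, chromosome 3, 34650405 to 34652461) went from 157 ± 5.41 CPM at DIV3 to 15.5 ± 0.329 at DIV11. Pax2 (ENSMUSG00000004231, chromosome 19, 44756045 to 44837871) went from 0.127 ± 0.0519 to 2.06 ± 0.617 CPM between DIV3 and DIV21.

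**Figure D1:**
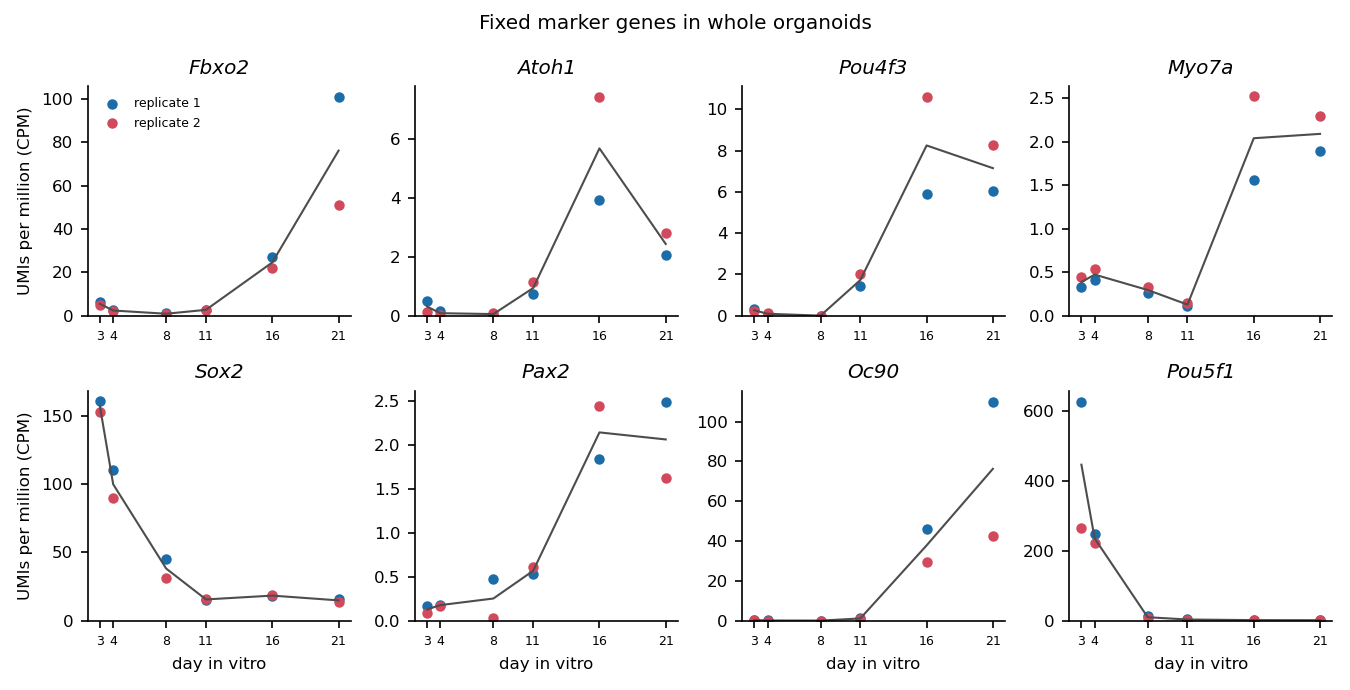
Level of 8 fixed marker genes in CPM (vertical axes) by day in vitro (horizontal axes), with a point for each library and a line through the mean of the 2 libraries of a day. Pou5f1 is highest at DIV3 and Fbxo2 and Oc90 are highest at DIV21, where Fbxo2 reaches 76.2 CPM and Oc90 76.3 CPM on average.

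Cells were grouped by 1 joint clustering, named after fixed marker lists, to ask which cell types the organoids hold at each day. Pluripotent-like cells made up 89.99% ± 8.18 (SD, n = 2) of retained cells at DIV3, 15.2% ± 1.36 at DIV4 (log2 fold change -2.57 ± 0.47, adjusted p = 9.41e-06) and 2.01% ± 0.91 at DIV8 (log2 fold change -2.92 ± 0.48, adjusted p = 1.24e-06). The fall from DIV3 to DIV4 was not called at clustering resolution 0.5 (log2 fold change -0.58, adjusted p = 0.247) or with doublets kept (-0.59, adjusted p = 0.36). Most DIV4 cells lay in unnamed cluster 0 (50.9% ± 2.93) and unnamed cluster 5 (24.1% ± 4.09), neither of which met the rule for a name. Cluster 0 had too few markers. In cluster 5 the non-neural ectoderm list (score 1.915) and the pluripotent list (score 1.81) were tied. A further 5.21% ± 1.22 lay in unnamed cluster 1. At DIV8 unnamed clusters 13 and 23 held 39.2% ± 12.2 and 15.5% ± 1.51 of cells and neuron-like cells 26.4% ± 2.63 (log2 fold change 9.27 ± 0.72, adjusted p = 5.74e-15). Non-neural ectoderm-like cells made up 10.7% ± 6.42, from 0 cells in both DIV4 libraries to 2517 cells over both DIV8 libraries (adjusted p = 8.61e-13). This rise depends on the naming rule, which left cluster 5 unnamed at DIV4. Endoderm-like cells were 3.99% ± 1.27 at DIV4 and 1.92% ± 0.0528 at DIV8.

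Mesenchyme-like cells, at 0.0114% ± 0.0161 on DIV8, were the largest class from DIV11 on, at 56.5% ± 1.38, 62.0% ± 2.10 and 53.8% ± 1.83 (log2 fold change 12 ± 0.74, adjusted p = 1.55e-17 for DIV11 against DIV8). Unnamed cluster 23, which held 15.5% of DIV8 cells, carried Twist1 of the mesenchyme list at 536 CPM against 191 in all other cells. Cluster 13 carried it at 237 against 215 CPM, and mesenchyme was the best-scoring list of neither cluster. The low DIV8 share rests on the naming rule and does not show that mesenchymal genes were absent. The change of mesenchyme-like cells from DIV11 to DIV16 did not pass (log2 fold change 0.13 ± 0.42, adjusted p = 0.976), but was called at resolution 2.0 (1.61) and with doublets kept (0.67). Epidermis-like cells were 8.05% ± 0.534 at DIV11, in cluster 11, 10.8% ± 0.586 at DIV16, in cluster 12, and 2.84% ± 1.16 at DIV21 (log2 fold change -1.93 ± 0.45, adjusted p = 0.00029 for DIV21 against DIV16). The change from DIV11 to DIV16 (log2 fold change 0.42 ± 0.43, adjusted p = 0.48) was called only at resolution 0.5 (1.51) and at resolution 2.0 (1.22). Neuron-like cells fell to 9.96% ± 0.66 at DIV11 (log2 fold change -1.40 ± 0.42, adjusted p = 0.00395). They fell further to 2.45% ± 0.119 at DIV16 (log2 fold change -2.02 ± 0.43, adjusted p = 8.19e-05) and 0.95% ± 0.511 at DIV21 (log2 fold change -1.37 ± 0.43, adjusted p = 0.00637). Without DIV11 replicate 1 the first of these falls gave adjusted p = 0.0669, and without DIV21 replicate 1 the last gave adjusted p = 0.158. Skeletal muscle-like cells rose to 4.92% ± 2.86 at DIV16 (log2 fold change 4.02 ± 0.52, adjusted p = 1.12e-08) and 11.3% ± 2.10 at DIV21 (log2 fold change 1.20 ± 0.45, adjusted p = 0.0214). The later step was not called without DIV16 replicate 2 (log2 fold change 0.70, adjusted p = 0.379) or without DIV21 replicate 1 (1.00, adjusted p = 0.0775).

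The inner ear classes appeared late and stayed small. Hair cell-like cells numbered 0 at DIV8, 13 and 12 at DIV11, 56 and 89 at DIV16 and 81 and 76 at DIV21 in replicates 1 and 2. Their share rose from 0.142% ± 0.0093 at DIV11 to 0.719% ± 0.139 at DIV16 (log2 fold change 2.33 ± 0.50, adjusted p = 0.000109). At DIV21 it was 0.915% ± 0.0885, which did not pass against DIV16 (log2 fold change 0.34 ± 0.44, adjusted p = 0.604). Otic epithelium-like cells were 0.0509% ± 0.0018, 2.10% ± 0.52 and 3.70% ± 1.75 of cells at these days (log2 fold change 5.32 ± 0.60, adjusted p = 3.32e-10 for DIV16 against DIV11). At resolution 0.5 the class also takes in 526 and 424 DIV11 cells, and the change from DIV11 to DIV16 turns to a log2 fold change of -0.76 (adjusted p = 0.128). The step to DIV21 did not pass (0.81 ± 0.44, adjusted p = 0.123), and was called without DIV21 replicate 2 (1.23, adjusted p = 0.0246). Unnamed clusters 16, 24 and 33 held 1.85% ± 1.38, 4.48% ± 0.896 and 3.35% ± 0.483 of DIV21 cells, and cluster 14 held 0.261% ± 0.112 of DIV8 cells. Clusters with few UMIs per cell held 20.1% ± 0.545, 10.4% ± 1.27 and 15.9% ± 0.143 of cells at DIV11, DIV16 and DIV21. Cells of similar depth at earlier days were largely not set apart, since the limit is relative to the median of each library. Median UMIs per cell were 1250 to 1622 in the low-UMI clusters, 1483 in cluster 13 and 1679 in neuron-like cluster 9. Over the named classes edgeR called 24 changes of share between consecutive days, 12 up and 12 down, and limma on log2 shares called 8. The calls that limma did not make include the pluripotent-like changes, the later neuron-like and muscle-like ones (such as adjusted p = 0.559 for muscle-like cells at DIV21) and the hair cell-like rise at DIV16 (adjusted p = 0.324).

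**Figure D2:**
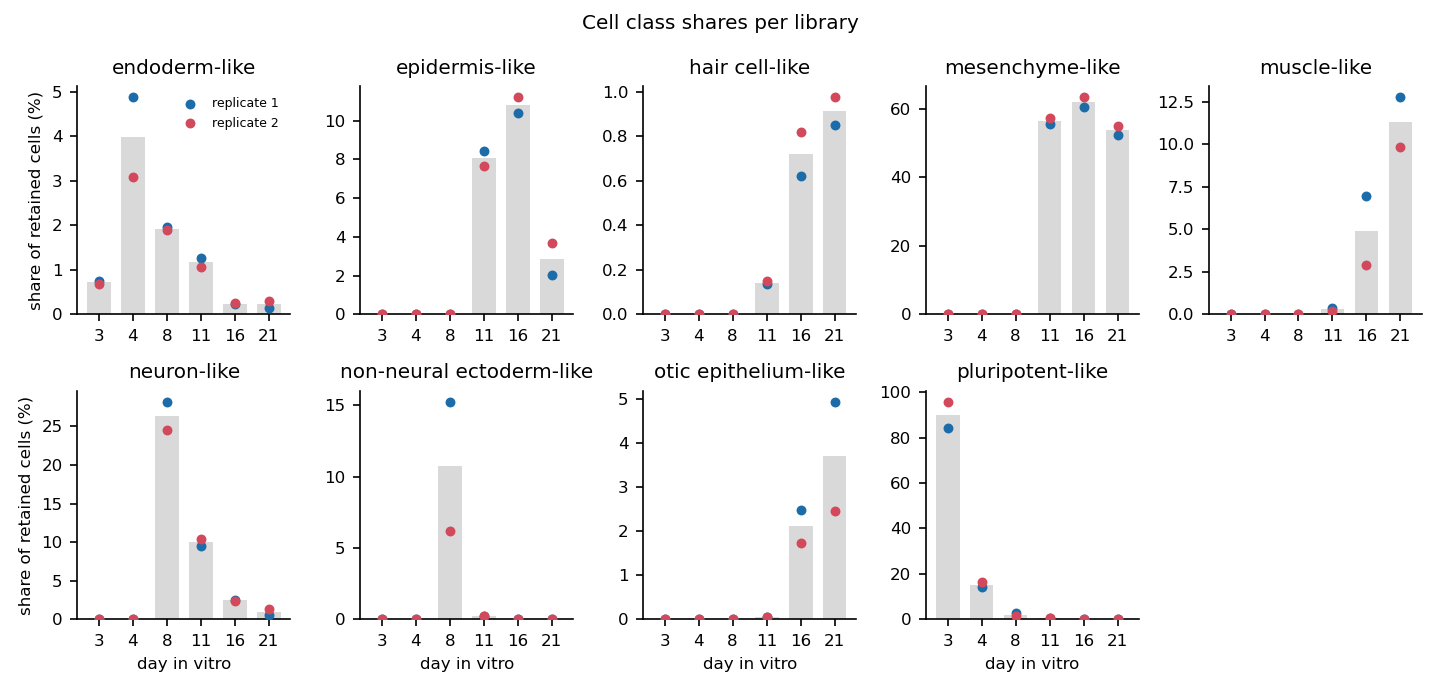
Share of retained cells in percent (vertical axes) of 9 cell classes by day in vitro (horizontal axes), with bars for the mean of 2 libraries and points for each library. Pluripotent-like cells make up 89.99% of cells at DIV3, mesenchyme-like cells 62.0% at DIV16 and hair cell-like cells 0.915% at DIV21.

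At DIV3 the organoids received 10 ng/mL BMP4 with 1 µM RepSox, which blocks TGF-beta receptors, and DIV4 against DIV3 asks how the aggregates answered. Of the fixed lists, non-neural ectoderm genes and BMP targets rose and formative and primed pluripotency genes fell. FGF and ERK targets and Nodal and TGF-beta targets also fell, but did not pass with an estimated correlation (adjusted p = 0.124 and 0.183). Hand1 (ENSMUSG00000037335), which BMP induces in extraembryonic and lateral mesoderm lineages, rose from 0.062 ± 0.087 to 154 ± 40.9 CPM (log2 fold change 10.44 ± 0.65, adjusted p = 1.31e-06). Gata3 (ENSMUSG00000015619), a factor of surface ectoderm and later of the ear, rose from 0.058 ± 0.082 to 54.4 ± 2.74 CPM (log2 fold change 9.03 ± 0.36, adjusted p = 5.95e-08). Tfap2a (ENSMUSG00000021359) rose from 2.70 ± 0.335 to 78.8 ± 4.02 CPM (log2 fold change 4.88 ± 0.17, adjusted p = 4.66e-08). Further ectodermal and BMP-responsive rises, as log2 fold changes, were Msx2 (8.93 ± 0.42), Msx1 (7.0 ± 0.48), Dlx5 (6.08 ± 0.30), Krt8 (4.10 ± 0.26), Id2 (2.88 ± 0.12), Smad6 (4.43 ± 0.20) and Bambi (2.85 ± 0.16). The placode genes Eya2 (5.09 ± 0.39), Dlx6 (5.35 ± 0.46) and Foxi2 (2 to 91 UMIs) rose with them. The remaining large rises were Flt1 (5.68 ± 0.38), Ccnd2 (5.22 ± 0.16) and Meis2 (4.91 ± 0.19). Of the Wnt target list Dkk1 (6.05 ± 0.36), Lgr5 (5.37 ± 0.26) and Axin2 (1.95 ± 0.16) rose, while 2 of its genes fell and the list did not pass with an estimated correlation (adjusted p = 0.0933). Pou3f1 (ENSMUSG00000090125), a factor of the formative state, fell from 273 ± 1.68 to 14.9 ± 2.18 CPM (log2 fold change -4.11 ± 0.55, adjusted p = 0.000276). Fgf5 (ENSMUSG00000029337), a marker of primed epiblast, fell from 51.1 ± 9.40 to 5.30 ± 0.3 CPM (log2 fold change -3.20 ± 0.29, adjusted p = 1.93e-05). Other falls were Dppa2 (-3.20 ± 0.40), Mt3 (-3.06 ± 0.37), Gadd45g (-2.77 ± 0.26), Gpx2 (-2.72 ± 0.35), Slc7a7 (-2.67 ± 0.23), Cbr3 (-2.56 ± 0.21), Dnmt3a (-1.67 ± 0.11), Dnmt3b (-1.56 ± 0.17), Etv5 (-1.87 ± 0.14) and Dusp6 (-1.25 ± 0.17). The Nodal antagonist and target Lefty1 fell from 11.5 ± 10.7 CPM to 0 counts at DIV4, at least 170.0-fold lower against a floor of 3 counts per library, a bound that rests largely on 1 of the DIV3 libraries (3.94 and 19.0 CPM). Pou5f1 did not pass (log2 fold change -0.85 ± 0.37, adjusted p = 0.107), with 626 and 266 CPM in the DIV3 libraries. Its fall was called without DIV3 replicate 2 (-1.35, adjusted p = 0.0137), with no filter on low counts (adjusted p = 0.0151) and with libraries thinned to the same UMI total (adjusted p = 0.0221). Sox2 fell by 0.58 ± 0.15 on the log2 scale (adjusted p = 0.0125) and Fbxo2 fell by 1.01 ± 0.31 (adjusted p = 0.0327). Sox2 did not pass without DIV4 replicate 1 (adjusted p = 0.0504) or DIV4 replicate 2 (adjusted p = 0.128). The Fbxo2 call was lost without DIV3 replicate 2 (adjusted p = 0.115), DIV4 replicate 1 (adjusted p = 0.0629) or DIV4 replicate 2 (adjusted p = 0.185).

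In all, edgeR called 5519 of 19664 genes, 2901 higher and 2618 lower at DIV4. The count fell to 3522 without DIV3 replicate 2, 2900 without DIV4 replicate 1 and 2659 without DIV4 replicate 2. Without DIV3 replicate 1, the library of 133 cells, the split turned to 2004 higher and 4091 lower. Of 41 fixed gene lists, camera called 12. Numbers of list genes that rose and fell when adjusted over the list alone are given, here and later, where they differ from those over all genes. BMP targets rose (11 rose, 0 fell, 1 did not pass, camera adjusted p = 8.41e-39). Non-neural ectoderm genes rose (9 rose, 0 fell, 2 did not pass, camera adjusted p = 6.96e-33). Formative and primed pluripotency genes fell (1 rose, 8 fell, 2 did not pass, camera adjusted p = 7.76e-06). These 3 lists also passed with an estimated correlation (adjusted p = 0.00852, 0.0202 and 0.0396). The others did not, at adjusted p = 0.0689 to 0.607 with an estimated correlation. Wnt targets rose (9 rose, 2 fell, 2 did not pass, 9 and 3 adjusted over the list alone, camera adjusted p = 7.66e-07). Cranial placode genes rose (5 rose, 2 fell, 2 did not pass, camera adjusted p = 0.000162). FGF and ERK targets fell (0 rose, 8 fell, 4 did not pass, 1 and 8 adjusted over the list alone, camera adjusted p = 4.30e-05). Nodal and TGF-beta targets fell (1 rose, 7 fell, 1 did not pass, camera adjusted p = 0.0002). Pluripotent genes fell (0 rose, 5 fell, 7 did not pass, camera adjusted p = 0.00884), a call lost without DIV3 replicate 1 (adjusted p = 0.0524). Neural crest and glia genes rose (3 rose, 1 fell, 5 did not pass, camera adjusted p = 0.00241). Notch pathway genes rose (4 rose, 1 fell, 7 did not pass, camera adjusted p = 0.0454), and both calls were lost without DIV3 replicate 2 (adjusted p = 0.107 and 0.11). Basement membrane and matrix genes rose (7 rose, 1 fell, 6 did not pass, camera adjusted p = 0.027), a call lost without DIV3 replicate 1 (adjusted p = 0.156). Cochlear sensory genes were called up (3 rose, 2 fell, 4 did not pass, camera adjusted p = 0.0118) with a median log2 fold change of 0.00 and a mean of 1.04. The DIV4 libraries are also those with most high-mitochondrial barcodes, and the test cannot separate this from the day.

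At DIV4 the organoids received 50 ng/mL FGF2 with 1 µM LDN193189, which blocks BMP receptors, and DIV8 against DIV4 spans the following days. Sensory neuroblast and mesenchyme genes rose and formative and primed pluripotency genes fell. Neuron, cranial placode and otic epithelium genes also rose and pluripotent genes fell, but these lists did not pass with an estimated correlation (adjusted p = 0.109, 0.0708, 0.249 and 0.233). Nhlh2 (ENSMUSG00000048540), a factor of newborn neurons, rose from 0.058 ± 0.028 to 57.1 ± 5.90 CPM (log2 fold change 10.08 ± 0.48, adjusted p = 4.30e-08). Tlx3 (ENSMUSG00000040610), a factor of sensory neurons, rose from 0.058 ± 0.028 to 44.9 ± 12 CPM (log2 fold change 9.73 ± 0.41, adjusted p = 1.98e-08). Col3a1 (ENSMUSG00000026043), a fibrillar collagen of mesenchyme, rose from 3 to 18907 UMIs (adjusted p = 4.22e-09). Other neuronal rises, as log2 fold changes, were Sst (12.71 ± 0.93), Rgs4 (10.28 ± 0.28), Pcdh17 (8.46 ± 0.21), Neurod1 (5.88 ± 0.24), Neurog1 (6.62 ± 0.41) and Isl1 (5.66 ± 0.35). Inka1 rose by 8.58 ± 0.30. Of placode and otic genes Eya2 (3.61 ± 0.22), Foxi2 (4.34 ± 0.24), Pax8 (5.64 ± 0.32) and Hmx2 (5.51 ± 0.52) rose. Mesenchymal rises were Prrx1 (6.73 ± 0.28), Twist1 (5.52 ± 0.24) and Col2a1 (5.45 ± 0.22). In the epidermal list Trp63 (3.69 ± 0.18) and Krt15 (3 to 585 UMIs) rose, with Krt5 at 0 counts in DIV4 and at least 44.8-fold higher at DIV8. Pou5f1 fell from 235 ± 20.0 to 9.62 ± 4.56 CPM (log2 fold change -4.51 ± 0.42, adjusted p = 5.96e-06). Nanog (ENSMUSG00000012396) fell from 51.8 ± 6.53 to 2.66 ± 0.619 CPM (log2 fold change -4.18 ± 0.37, adjusted p = 3.61e-06). Hand1 fell from 154 ± 40.9 to 1.27 ± 0.575 CPM (log2 fold change -6.81 ± 0.45, adjusted p = 4.12e-07), with Pim2 (-5.24 ± 0.14), Flt1 (-4.75 ± 0.32), Car4 (-4.57 ± 0.26), Phlda2 (-4.33 ± 0.36), Gdf3 (-3.91 ± 0.45) and Lef1 (-3.61 ± 0.15) lower as well. Sox2 fell by 1.29 ± 0.15 on the log2 scale (adjusted p = 2.70e-05). Fbxo2 fell by 1.28 ± 0.32 (adjusted p = 0.00623), which did not pass without DIV8 replicate 2 (adjusted p = 0.0525) or with libraries thinned to the same UMI total (-0.33, adjusted p = 0.688). Pax2 did not pass (0.59 ± 0.81, adjusted p = 0.576), with 0.468 and 0.034 CPM in the DIV8 libraries. It was called lower without DIV8 replicate 1 (-2.19, adjusted p = 0.0253) and higher without DIV8 replicate 2 (1.46, adjusted p = 0.0246).

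Here edgeR called 9919 genes, 5493 higher and 4426 lower at DIV8, with 6266 in all without DIV4 replicate 1 and 2779 lower without DIV8 replicate 2. Of the 41 lists 18 were called, and 4 passed with an estimated correlation. Mesenchyme genes rose (12 rose, 0 fell, 1 did not pass, camera adjusted p = 6.96e-18). Sensory neuroblast genes rose (7 rose, 1 fell, 1 did not pass, camera adjusted p = 3.23e-05). These lists stood at adjusted p = 0.0496 each with an estimated correlation. Wnt targets fell (3 rose, 7 fell, 3 did not pass, camera adjusted p = 7.91e-06). Formative and primed pluripotency genes fell (1 rose, 8 fell, 2 did not pass, 2 and 8 adjusted over the list alone, camera adjusted p = 3.19e-06). The falling lists stood at adjusted p = 0.0435 each with an estimated correlation.

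The remaining 14 gave adjusted p = 0.0708 to 0.57 with an estimated correlation. Neuron genes rose (10 rose, 0 fell, 1 did not pass, camera adjusted p = 1.91e-09). Otic epithelium genes rose (8 rose, 1 fell, 4 did not pass, camera adjusted p = 0.000227). Cranial placode genes rose (7 rose, 2 fell, 0 did not pass, camera adjusted p = 0.000714). Cartilage genes rose (7 rose, 1 fell, 2 did not pass, camera adjusted p = 0.000148). Olfactory genes rose (5 rose, 0 fell, 2 did not pass, camera adjusted p = 0.00188). Epidermis genes rose (7 rose, 0 fell, 4 did not pass, camera adjusted p = 0.00227). FGF and ERK targets rose after FGF2 was given (10 rose, 0 fell, 2 did not pass, camera adjusted p = 9.29e-05). Retinoic acid pathway genes rose (6 rose, 2 fell, 3 did not pass, 7 and 2 adjusted over the list alone, camera adjusted p = 0.000749). Pluripotent genes fell (0 rose, 12 fell, 0 did not pass, camera adjusted p = 1.84e-06). Naive pluripotency genes fell (0 rose, 10 fell, 1 did not pass, 0 and 11 adjusted over the list alone, camera adjusted p = 0.000148). S phase genes fell (0 rose, 13 fell, 3 did not pass, camera adjusted p = 5.37e-05). Notch pathway genes rose (7 rose, 2 fell, 3 did not pass, camera adjusted p = 0.0423), a call lost without DIV4 replicate 1 (adjusted p = 0.0753) or DIV4 replicate 2 (adjusted p = 0.0575). Basement membrane and matrix genes rose (10 rose, 4 fell, 0 did not pass, camera adjusted p = 0.0338), a call lost without DIV8 replicate 1 (adjusted p = 0.0946). Dissociation response genes, which cells turn on while tissue is taken apart, also rose (13 rose, 0 fell, 1 did not pass, camera adjusted p = 1.91e-09). DIV8 is the first day whose organoids were treated with thermolysin.

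**Figure D3:**
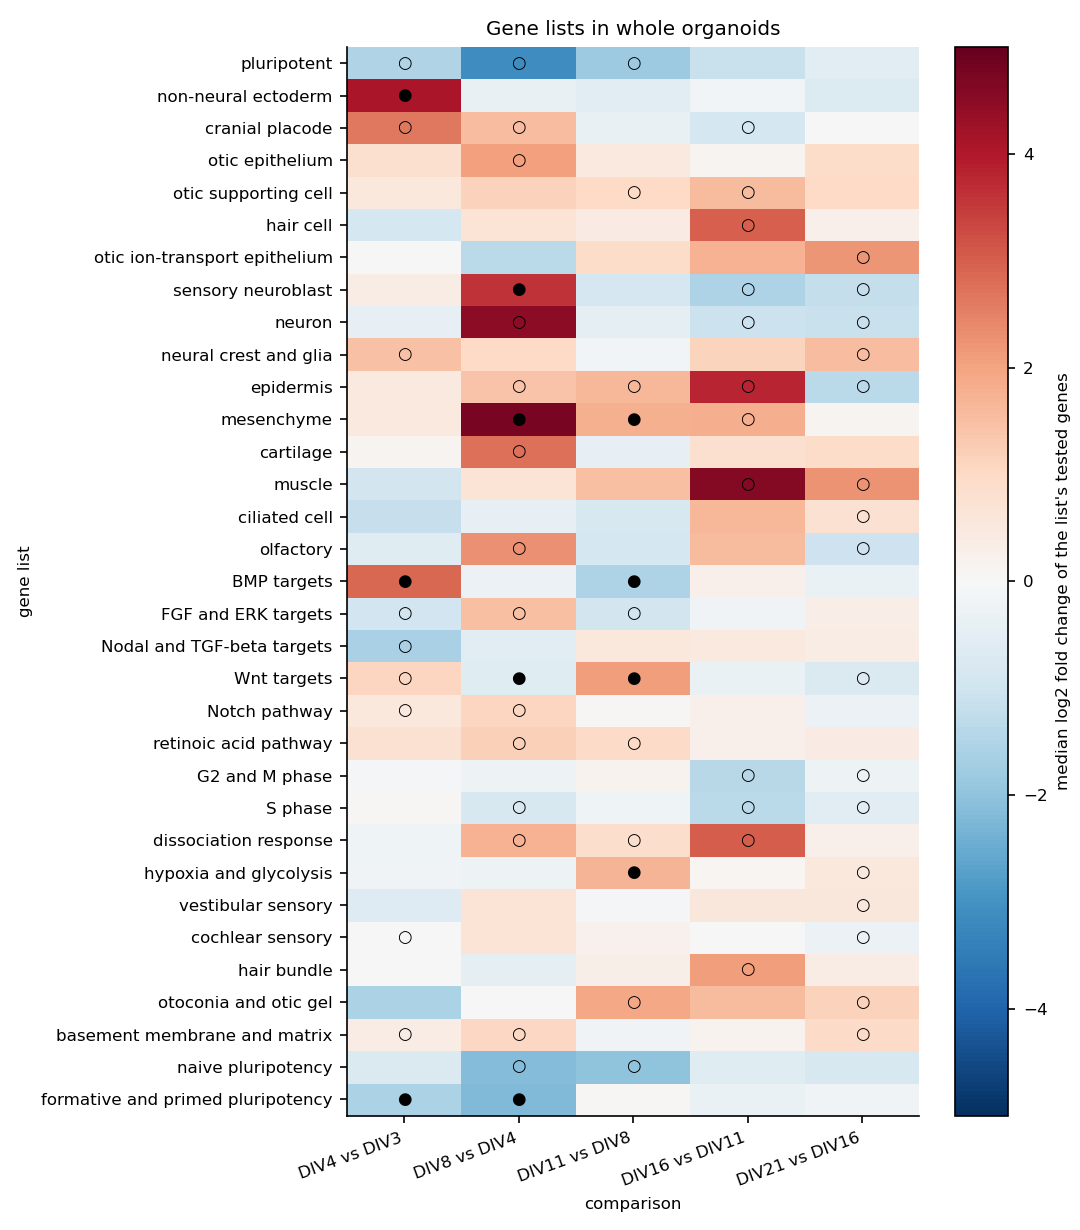
Median log2 fold change of the tested genes of each fixed list (colour scale) for lists (vertical axis) and comparisons of consecutive days (horizontal axis). Open circles mark a camera adjusted p under 0.05 and filled circles a call that also passed with an estimated correlation, 11 of the 70 calls.

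At DIV8 the organoids moved to maturation medium with 3 µM CHIR99021, which activates Wnt signalling, and DIV11 against DIV8 asks what followed. Wnt targets, mesenchyme genes and hypoxia and glycolysis genes rose and BMP targets fell. FGF and ERK targets also fell, but did not pass with an estimated correlation (adjusted p = 0.0631). Lef1 (ENSMUSG00000027985), a target and effector of Wnt signalling, rose from 2.22 ± 0.141 to 38.1 ± 3.09 CPM (log2 fold change 4.02 ± 0.15, adjusted p = 1.58e-08), with Axin2 (2.81 ± 0.15) and Apcdd1 (4.94 ± 0.23) also higher as log2 fold changes. Foxd1 (ENSMUSG00000078302), a factor of mesenchyme, rose from 0.453 ± 0.191 to 63.5 ± 1.54 CPM (log2 fold change 7.06 ± 0.32, adjusted p = 6.10e-08). Col1a1 (ENSMUSG00000001506) rose from 1.11 ± 0.301 to 85.2 ± 6.67 CPM (log2 fold change 6.18 ± 0.27, adjusted p = 4.46e-08). Other rises included Emx2 (5.26 ± 0.27), Pcdh10 (5.10 ± 0.14), Efemp1 (5.04 ± 0.41), Tac1 (4.77 ± 0.35), Fbln2 (4.65 ± 0.15) and Lum (4.62 ± 0.17). So did the basal keratinocyte genes Krt14 (4.50 ± 0.39) and Krt5 (3.83 ± 0.34) and the low-oxygen genes Car9 (5.65 ± 0.23) and Vegfa (2.55 ± 0.15). Pou4f3 passed (adjusted p = 9.44e-06), from 1 count over both DIV8 libraries to 280 at DIV11. Oc90, at 0 counts in DIV8, was at least 30.7-fold higher (adjusted p = 0.000635). Atoh1 rose by a log2 fold change of 3.89 ± 0.68 (adjusted p = 0.00112) and Fbxo2 by 1.5 ± 0.31 (adjusted p = 0.00311), and neither passed with libraries thinned to the same UMI total (adjusted p = 0.12 and 0.549). Tagln (ENSMUSG00000032085) and Acta2 fell, Tagln from 108 ± 62.1 to 3.78 ± 1.28 CPM (log2 fold change -4.89 ± 0.41, adjusted p = 7.62e-06) and Acta2 by 3.99 ± 0.52. Tagln was among the leading genes of the non-neural ectoderm-like cluster. Further falls were Hopx (-4.85 ± 0.32), Msx2 (-4.48 ± 0.26), Sct (-4.15 ± 0.26), Rbp4 (-4.05 ± 0.26), Prtg (-3.23 ± 0.22) and Tbx3 (-3.22 ± 0.25). Also lower were the BMP targets Id4 (-2.50 ± 0.16) and Id1 (-1.65 ± 0.14), the FGF targets Etv5 (-2.71 ± 0.14) and Spry1 (-2.42 ± 0.15) and Sox2 (-1.37 ± 0.15). Myo7a was called lower (-1.29 ± 0.40, adjusted p = 0.0285), but lost the call without any 1 of the DIV8 and DIV11 libraries (adjusted p = 0.0528 to 0.163). With libraries thinned to the same UMI total its direction turned (1.44, adjusted p = 0.395), but even before thinning Myo7a had only 51 UMIs at DIV8 and 21 at DIV11. Pou5f1 fell by 1.71 ± 0.40 (adjusted p = 0.00708), not called without DIV8 replicate 1 (adjusted p = 0.0875) or DIV11 replicate 2 (adjusted p = 0.0554).

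Between these days edgeR called 6798 genes, 3253 higher and 3545 lower at DIV11. It called 4294, 4221, 4135 and 3694 without DIV8 replicate 1, DIV8 replicate 2, DIV11 replicate 1 and DIV11 replicate 2. Camera called 12 lists, and 4 passed with an estimated correlation. Wnt targets rose (12 rose, 1 fell, 0 did not pass, camera adjusted p = 3.82e-20). Hypoxia and glycolysis genes rose (13 rose, 0 fell, 2 did not pass, camera adjusted p = 4.45e-20). Both passed, at adjusted p = 0.00218 and 0.00793 with an estimated correlation. Mesenchyme genes rose (11 rose, 2 fell, 0 did not pass, camera adjusted p = 9.46e-16). BMP targets fell (1 rose, 10 fell, 1 did not pass, camera adjusted p = 6.39e-11). These also passed, at adjusted p = 0.0395 and 0.0172 with an estimated correlation.

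The other 8 gave adjusted p = 0.0631 to 0.472 with an estimated correlation. FGF and ERK targets fell (1 rose, 8 fell, 3 did not pass, 1 and 10 adjusted over the list alone, camera adjusted p = 1.92e-07). Pluripotent genes fell (0 rose, 10 fell, 2 did not pass, camera adjusted p = 0.00016). Naive pluripotency genes fell (1 rose, 8 fell, 2 did not pass, 1 and 9 adjusted over the list alone, camera adjusted p = 0.000795). Epidermis genes rose (6 rose, 0 fell, 5 did not pass, 7 and 0 adjusted over the list alone, camera adjusted p = 9.56e-07). Retinoic acid pathway genes rose (6 rose, 1 fell, 4 did not pass, camera adjusted p = 0.00157). Otic supporting cell genes rose (4 rose, 0 fell, 7 did not pass, camera adjusted p = 0.0123). Otoconia and otic gel genes rose (5 rose, 1 fell, 6 did not pass, camera adjusted p = 0.041), a call lost without DIV8 replicate 1 (adjusted p = 0.0719) or DIV8 replicate 2 (adjusted p = 0.0714). Dissociation response genes rose again (9 rose, 0 fell, 5 did not pass, camera adjusted p = 8.17e-10). The labels name no dissociation enzyme for DIV11.

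No factor is named in the labels after DIV8, so DIV16 against DIV11 asks how the organoids matured. Hair cell, otic supporting cell, epidermis and muscle lists rose and S phase, G2 and M phase and neuron lists fell by camera. None passed with an estimated correlation. Fbxo2 rose from 2.73 ± 0.122 to 24.6 ± 3.50 CPM (log2 fold change 3.03 ± 0.28, adjusted p = 6.08e-06). Oc90 rose from 1.07 ± 0.284 to 37.8 ± 12 CPM (log2 fold change 4.97 ± 0.44, adjusted p = 8.01e-06). Myo7a rose from 0.128 ± 0.018 to 2.04 ± 0.682 CPM (log2 fold change 3.85 ± 0.37, adjusted p = 8.45e-06). Atoh1 rose from 0.941 ± 0.303 to 5.68 ± 2.49 CPM (log2 fold change 2.47 ± 0.47, adjusted p = 0.00121). Pou4f3 rose from 1.73 ± 0.386 to 8.25 ± 3.30 CPM (log2 fold change 2.13 ± 0.32, adjusted p = 0.000221). Further hair cell and bundle rises, as log2 fold changes, were Acbd7 (4.65 ± 0.27), Pvalb (4.28 ± 0.29), Lhfpl5 (4.74 ± 0.32), Otof (3 to 686 UMIs) and Espnl (5.0 ± 0.47). The otic genes Agr3 (4.39 ± 0.43) and Tectb (3 to 119 UMIs) rose. Calm4 (ENSMUSG00000033765), Sprr1b and Krt16 of the cornified layer rose, Calm4 from 0.053 ± 0.015 to 330.3 ± 162 CPM (log2 fold change 12.40 ± 0.60, adjusted p = 8.39e-08). Other keratinocyte rises were Ly6d (2 to 33703 UMIs), Sprr1b (11.93 ± 0.46), Cnfn (2 to 7271 UMIs), Krt77 (10.94 ± 0.48), Krt16 (9.99 ± 0.78), Dmkn (9.94 ± 0.61) and Krt1 (9.14 ± 0.56), with the chemokine gene Ccl20 (3 to 7815 UMIs). Of mesenchymal and muscle genes Dcn (5.38 ± 0.23), Postn (5.19 ± 0.34), Myod1 (4.69 ± 0.29) and Ckm (5.56 ± 0.43) rose. Neurod1 (ENSMUSG00000034701), a factor of neuroblasts, fell from 66.8 ± 14.3 to 2.92 ± 0.267 CPM (log2 fold change -4.65 ± 0.22, adjusted p = 8.39e-08). Sst (-5.37 ± 0.59), Nhlh2 (-2.99 ± 0.27), Neurog1 (-4.76 ± 0.34) and Ppp1r17 (-4.15 ± 0.32) fell as well. Hmga2 (ENSMUSG00000056758), a chromatin protein of growing embryonic cells, fell from 209 ± 1.10 to 18.2 ± 5.20 CPM (log2 fold change -3.66 ± 0.25, adjusted p = 7.41e-07), as did Hist1h2ap (-3.01 ± 0.46), Hist1h3c (-2.93 ± 0.36), Hist1h2ae (-2.80 ± 0.32) and Ube2c (-1.62 ± 0.13). The placode gene Foxi2 fell from 0.519 ± 0.116 CPM to 0 counts, at least 15.3-fold lower. Sox2 did not pass (0.10 ± 0.15, adjusted p = 0.601). The rise of Pax2 (1.78 ± 0.57, adjusted p = 0.0235) was not called without DIV11 replicate 1 (adjusted p = 0.126), DIV11 replicate 2 (adjusted p = 0.0913) or DIV16 replicate 2 (adjusted p = 0.1).

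From DIV11 to DIV16 edgeR called 9365 genes, 5104 higher and 4261 lower at DIV16, with 2839 lower without DIV16 replicate 2. Of the 12 lists that camera called none passed with an estimated correlation (adjusted p = 0.149 to 0.533). Hair cell genes rose (17 rose, 0 fell, 3 did not pass, 19 and 0 adjusted over the list alone, camera adjusted p = 2.65e-09). Hair bundle genes rose (21 rose, 1 fell, 6 did not pass, 23 and 1 adjusted over the list alone, camera adjusted p = 2.19e-06). Otic supporting cell genes rose (10 rose, 1 fell, 0 did not pass, camera adjusted p = 0.00738). Epidermis genes rose (10 rose, 0 fell, 1 did not pass, camera adjusted p = 1.30e-08). Muscle genes rose (10 rose, 0 fell, 0 did not pass, camera adjusted p = 2.58e-08). Mesenchyme genes rose (8 rose, 1 fell, 4 did not pass, 8 and 2 adjusted over the list alone, camera adjusted p = 7.77e-07).

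S phase genes fell (0 rose, 16 fell, 0 did not pass, camera adjusted p = 4.05e-17). G2 and M phase genes fell (0 rose, 16 fell, 0 did not pass, camera adjusted p = 3.14e-13). Cranial placode genes fell (0 rose, 6 fell, 3 did not pass, 0 and 9 adjusted over the list alone, camera adjusted p = 0.00214). Sensory neuroblast genes fell (2 rose, 5 fell, 2 did not pass, camera adjusted p = 0.008). Neuron genes fell (1 rose, 6 fell, 4 did not pass, 1 and 7 adjusted over the list alone, camera adjusted p = 0.0215). Beside these, every tested gene of the dissociation response rose (14 rose, 0 fell, 0 did not pass, camera adjusted p = 3.77e-19), such as Fos (3.34 ± 0.15) and Junb (3.84 ± 0.17).

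The last comparison, DIV21 against DIV16, asks what changed as the organoids aged without a further factor. Epidermis and neuron lists fell and muscle, basement membrane and matrix, and otic ion-transport epithelium lists rose by camera. None passed with an estimated correlation. Fbxo2 rose from 24.6 ± 3.50 to 76.2 ± 35.4 CPM (log2 fold change 1.62 ± 0.25, adjusted p = 0.00117). Atoh1 (-1.22 ± 0.44, adjusted p = 0.0755), Pou4f3 (-0.21 ± 0.30, adjusted p = 0.677) and Myo7a (0.03 ± 0.29, adjusted p = 0.96) did not pass. Nor did Sox2 (-0.31 ± 0.15, adjusted p = 0.166) and Oc90 (0.99 ± 0.35, adjusted p = 0.0705). A rise of Oc90 was called with a replicate block (0.90, adjusted p = 0.0042), no filter on low counts (adjusted p = 0.00699), libraries thinned to the same UMI total (adjusted p = 0.0428) and without DIV21 replicate 2 (1.49, adjusted p = 0.00325). A fall of Atoh1 was called with no filter on low counts (-1.22, adjusted p = 0.0182). Foxi1 (1 to 121 UMIs), the factor of endolymphatic ion-transport cells, rose. Of the ion-transport genes, Slc26a4 (ENSMUSG00000020651) rose from 0.266 ± 0.053 to 1.53 ± 0.745 CPM (log2 fold change 2.50 ± 0.45, adjusted p = 0.00285) and Atp6v1b1 by 2.26 ± 0.32. C3 (ENSMUSG00000024164), of the complement system, rose from 0.718 ± 0.111 to 74.9 ± 24.9 CPM (log2 fold change 6.71 ± 0.31, adjusted p = 5.39e-07), with Saa3 (7.05 ± 0.52) and Serpina3n (4.32 ± 0.37) beside it. The lung surfactant gene Sftpc rose by 9.10 ± 0.36. Other rises were Fabp4 (6.48 ± 0.55), Wfdc18 (5.72 ± 0.53), Ckm (5.05 ± 0.26), Acta1 (2.87 ± 0.44), Col4a1 (1.48 ± 0.19), Spp1 (3.11 ± 0.30) and Otoa (3.14 ± 0.49). Hp rose by 3.99 ± 0.96 (adjusted p = 0.0151), which DESeq2 did not call (adjusted p = 0.19) and which was lost without DIV21 replicate 1 (adjusted p = 0.0614). Krt1 (ENSMUSG00000046834) fell from 344 ± 143 to 1.29 ± 1.02 CPM (log2 fold change -8.07 ± 0.53, adjusted p = 7.58e-06). Krt10 (ENSMUSG00000019761) fell from 698 ± 308 to 37.8 ± 4.31 CPM (log2 fold change -4.21 ± 0.28, adjusted p = 7.58e-06). Further falls were Krt77 (-8.96 ± 0.40), Ly6g6c (-5.62 ± 0.50), Lor (-5.40 ± 0.39), Calm4 (-4.47 ± 0.37), Aqp3 (-3.68 ± 0.53) and Krt15 (-3.68 ± 0.27). Lower too were the neuronal genes Neurod1 (-2.39 ± 0.26) and Nefl (-2.37 ± 0.28), the Wnt target genes Lgr5 (-1.43 ± 0.15) and Lef1 (-1.03 ± 0.13) and Insm1 (-3.06 ± 0.22), Fgf20 (-2.42 ± 0.39) and Tectb (-3.60 ± 0.61).

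In this interval edgeR called 4026 genes, 2266 higher and 1760 lower at DIV21. It called 2357 without DIV16 replicate 1, 1965 without DIV16 replicate 2 and 2306 without DIV21 replicate 1. Camera called 16 lists and none passed with an estimated correlation (adjusted p = 0.118 to 0.566). Otic ion-transport epithelium genes rose (7 rose, 0 fell, 2 did not pass, camera adjusted p = 0.000753). Otoconia and otic gel genes rose (8 rose, 1 fell, 3 did not pass, 9 and 2 adjusted over the list alone, camera adjusted p = 0.00143). Vestibular sensory genes rose (5 rose, 1 fell, 4 did not pass, 7 and 1 adjusted over the list alone, camera adjusted p = 0.0282), a call lost without DIV16 replicate 1 (adjusted p = 0.0631). Cochlear sensory genes fell (1 rose, 3 fell, 5 did not pass, 2 and 3 adjusted over the list alone, camera adjusted p = 0.0254). Basement membrane and matrix genes rose (12 rose, 0 fell, 2 did not pass, 13 and 0 adjusted over the list alone, camera adjusted p = 1.43e-10). Muscle genes rose (10 rose, 0 fell, 0 did not pass, camera adjusted p = 6.81e-09). Hypoxia and glycolysis genes rose (8 rose, 0 fell, 7 did not pass, 11 and 0 adjusted over the list alone, camera adjusted p = 3.11e-05).

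Epidermis genes fell (0 rose, 8 fell, 3 did not pass, 0 and 9 adjusted over the list alone, camera adjusted p = 2.07e-11). Neuron genes fell (0 rose, 6 fell, 5 did not pass, 0 and 7 adjusted over the list alone, camera adjusted p = 6.23e-05). Olfactory genes fell (0 rose, 4 fell, 3 did not pass, camera adjusted p = 0.0157). Wnt targets fell (1 rose, 9 fell, 3 did not pass, 2 and 10 adjusted over the list alone, camera adjusted p = 3.30e-05). S phase genes fell (0 rose, 14 fell, 2 did not pass, camera adjusted p = 3.71e-07). Neural crest and glia genes rose (5 rose, 1 fell, 3 did not pass, 6 and 1 adjusted over the list alone, camera adjusted p = 0.0271). Ciliated cell genes rose (3 rose, 0 fell, 5 did not pass, 5 and 0 adjusted over the list alone, camera adjusted p = 0.0254). Sensory neuroblast genes fell (1 rose, 3 fell, 5 did not pass, 1 and 4 adjusted over the list alone, camera adjusted p = 0.0254). These last 3 calls were lost without DIV16 replicate 1 (adjusted p = 0.0631, 0.0801 and 0.0706) or DIV21 replicate 2 (adjusted p = 0.212, 0.0917 and 0.0723). G2 and M phase genes fell (0 rose, 5 fell, 11 did not pass, 0 and 6 adjusted over the list alone, camera adjusted p = 0.0462), a call lost without DIV16 replicate 1 (adjusted p = 0.536). With libraries thinned to the smallest total, edgeR called 3230, 6124, 3343, 5557 and 1873 genes in the whole-organoid comparisons by day.

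Counts were next summed within a class, which removes changes in the share of that class, to ask how each class changed. Within hair cell-like cells from DIV16 to DIV21 camera called lists for synapses, ciliated cells and the hair bundle up and the Notch pathway down, none of which passed with an estimated correlation (adjusted p = 0.205 to 0.266). Ocm, a calcium-binding protein gene of hair cells, rose from 13.1 ± 8.18 to 249 ± 260.1 CPM (log2 fold change 4.34 ± 0.69, adjusted p = 0.00103). Gpx2 rose from 20.4 ± 2.12 to 382 ± 86.7 CPM (log2 fold change 4.18 ± 0.22, adjusted p = 4.82e-08). Lcn2, at 0 counts in DIV16, was at least 28.6-fold higher, with a DIV21 mean of 64.7 ± 72.0 CPM whose SD exceeds it. Mt2 (3.76 ± 0.40) and AI593442 (3.50 ± 0.39) rose as well. Oc90 fell from 131 ± 56.5 to 6.63 ± 3.65 CPM (log2 fold change -4.34 ± 0.37, adjusted p = 1.15e-05). Atoh1 fell from 291 ± 10.6 to 151 ± 5.92 CPM (log2 fold change -0.98 ± 0.16, adjusted p = 0.00131). Other falls were Asprv1 (145 to 1 UMIs), Npy (-5.15 ± 0.50), Cstdc5 (-4.62 ± 0.60) and Dkk2 (-3.52 ± 0.34), where Asprv1 and Cstdc5 are also transcripts of keratinocytes. Fbxo2 (0.42 ± 0.14, adjusted p = 0.0762), Pou4f3 (-0.09 ± 0.15, adjusted p = 0.794) and Myo7a (0.11 ± 0.18, adjusted p = 0.765) did not pass. Fbxo2 was called without DIV21 replicate 1 (0.46, adjusted p = 0.00252) or DIV21 replicate 2 (0.39, adjusted p = 0.011). In this class edgeR called 892 genes. It called 547 without DIV16 replicate 1, 517 without DIV16 replicate 2, 1344 without DIV21 replicate 1 and 1741 without DIV21 replicate 2, of which 445, 433, 752 and 784 were among the 892, and DESeq2 called 358. A replicate block gave 567. List tests within classes were added after the data were seen, and none passed with an estimated correlation in any class. In hair cell-like cells the list for hair cell synapse and excitability rose (8 rose, 0 fell, 7 did not pass, 11 and 0 adjusted over the list alone, camera adjusted p = 9.62e-14). Ciliated cell genes rose (7 rose, 0 fell, 1 did not pass, 8 and 0 adjusted over the list alone, camera adjusted p = 4.79e-11). Hair bundle genes rose (9 rose, 0 fell, 18 did not pass, 13 and 0 adjusted over the list alone, camera adjusted p = 2.12e-07). Notch pathway genes fell (0 rose, 4 fell, 7 did not pass, 0 and 8 adjusted over the list alone, camera adjusted p = 5.51e-07). So did lists of neighbouring cell types, among them otic supporting cell (0 rose, 3 fell, 5 did not pass, 0 and 4 adjusted over the list alone, camera adjusted p = 0.00107) and otoconia and otic gel (1 rose, 3 fell, 4 did not pass, camera adjusted p = 0.00274). Mesenchyme genes (0 rose, 2 fell, 8 did not pass, 0 and 3 adjusted over the list alone, camera adjusted p = 0.00308) and otic epithelium genes (0 rose, 2 fell, 5 did not pass, 2 and 2 adjusted over the list alone, camera adjusted p = 0.0198) were called down as well. With 56 to 89 cells per library, the counts in this class rest on 1113600 to 1646619 UMIs.

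Otic epithelium-like cells lost their proliferation genes between DIV16 and DIV21 and gained Fbxo2. Fbxo2 rose from 355 ± 62.7 to 899.8 ± 68.0 CPM (log2 fold change 1.30 ± 0.18, adjusted p = 0.00274) and Oc90 did not pass (0.20 ± 0.17, adjusted p = 0.453). Cdk1 fell from 104 ± 24.5 to 5.0 ± 0.578 CPM (log2 fold change -4.45 ± 0.26, adjusted p = 0.00012). Top2a fell from 125 ± 29.0 to 7.30 ± 0.432 CPM (log2 fold change -4.12 ± 0.24, adjusted p = 0.00012), with Ube2c (-4.40 ± 0.55), Pclaf (-4.36 ± 0.25), Ccnb2 (-4.07 ± 0.51) and Prc1 (-4.01 ± 0.38) lower as well. Lcn2 rose from 1.25 ± 0.119 to 409.7 ± 65.4 CPM (log2 fold change 8.26 ± 0.29, adjusted p = 5.79e-06). Fshb (3 to 447 UMIs), Hp (5.97 ± 0.69), Tspan8 (5.37 ± 0.70), Cst6 (5.16 ± 0.27) and Trdn (4.95 ± 0.35) rose as well. Sox2 fell by 0.92 ± 0.24 (adjusted p = 0.0298), not called without DIV16 replicate 2 (adjusted p = 0.192) or DIV21 replicate 1 (adjusted p = 0.168). G2 and M phase genes fell (0 rose, 16 fell, 0 did not pass, camera adjusted p = 2.76e-40, adjusted p = 0.597 with an estimated correlation). S phase genes fell (0 rose, 16 fell, 0 did not pass, camera adjusted p = 3.15e-24). Notch pathway genes fell (1 rose, 6 fell, 5 did not pass, 1 and 8 adjusted over the list alone, camera adjusted p = 4.49e-05). The S phase and Notch lists did not pass with an estimated correlation either. Dissociation response genes rose (12 rose, 0 fell, 2 did not pass, 14 and 0 adjusted over the list alone, camera adjusted p = 1.78e-09, adjusted p = 0.597 with an estimated correlation). Here edgeR called 2076 genes, 1307 without DIV16 replicate 2 and 656 without DIV21 replicate 1, while DESeq2 called 1329 and a replicate block gave 3399. DIV16 could not be compared with DIV11 in this class, which held 5 and 4 DIV11 cells.

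**Figure D4:**
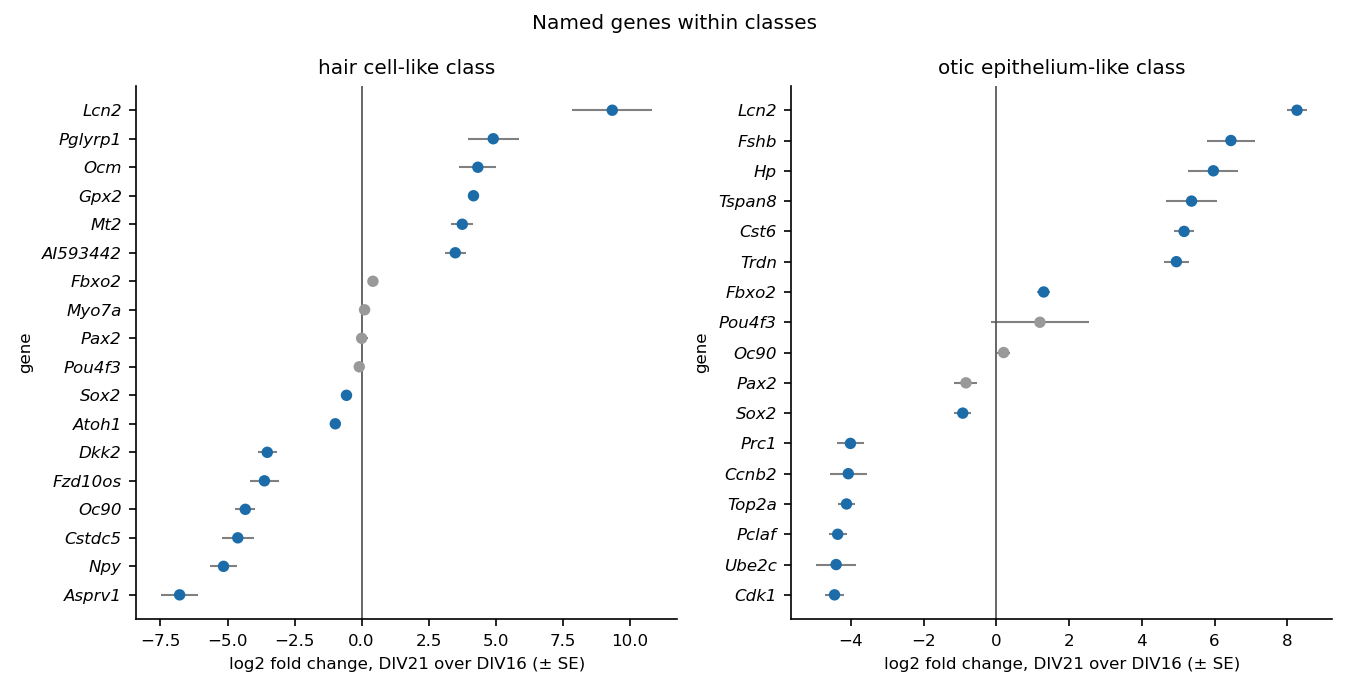
Log2 fold change from DIV16 to DIV21 with its standard error (horizontal axes) of the named genes (vertical axes) within hair cell-like and otic epithelium-like cells, n = 2 libraries per day. Blue points have an adjusted p under 0.05 and grey points do not, and Oc90 is at -4.34 in hair cell-like and 0.20 in otic epithelium-like cells.

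In mesenchyme-like cells edgeR called 10020 genes from DIV11 to DIV16 and 5052 from DIV16 to DIV21. It called 3111 in the later step without DIV16 replicate 1 and 2898 without DIV16 replicate 2. The clusters holding the class differ between the days, such as cluster 19 with 5805 DIV11 and 37 DIV16 cells, cluster 22 with 8364 DIV16 and 275 DIV21 cells and cluster 28 with 484 and 5597. A change of cells and a replacement of subpopulations are therefore not separated. In the first step Sfrp4 (8.98 ± 0.26), Clec3b (8.42 ± 0.24), Ccl2 (9.70 ± 0.65), Scg2 (8.22 ± 0.28) and Aspn (7.68 ± 0.30) rose, and so did the keratinocyte transcript Cstdc5 (1 to 4050 UMIs). Hmga2 (-3.91 ± 0.19), Hist1h2ap (-3.40 ± 0.48), Hist1h3e (-3.07 ± 0.18) and Fndc3c1 (-2.94 ± 0.12) fell. In the second C3 rose from 0.574 ± 0.384 to 132 ± 33.3 CPM (log2 fold change 7.94 ± 0.35, adjusted p = 2.42e-06), with Fabp4 (8.82 ± 0.22), Chil1 (8.28 ± 0.41), Hp (7.67 ± 0.63), Saa3 (7.41 ± 0.73) and Lcn2 (6.83 ± 0.53). Cstdc5 (-4.05 ± 0.26), Nnat (-3.12 ± 0.13), Ccnd1 (-2.71 ± 0.22), Nefl (-2.28 ± 0.16), Bex2 (-2.05 ± 0.17) and Sox11 (-1.95 ± 0.10) fell. Hypoxia and glycolysis genes rose in the second step (15 rose, 0 fell, 0 did not pass, camera adjusted p = 1.80e-30, adjusted p = 0.135 with an estimated correlation). Lists of other cell types moved in the class as well. In the first step epidermis genes (10 rose, 0 fell, 0 did not pass, camera adjusted p = 0.00253) and muscle genes (9 rose, 0 fell, 1 did not pass, camera adjusted p = 0.0165) rose. In the second epidermis genes fell (1 rose, 7 fell, 2 did not pass, camera adjusted p = 0.00726) and muscle genes rose (9 rose, 0 fell, 1 did not pass, 10 and 0 adjusted over the list alone, camera adjusted p = 5.38e-10). None of these calls passed with an estimated correlation. In epidermis-like cells the epidermis list rose from DIV11 to DIV16 (10 rose, 0 fell, 1 did not pass, 11 and 0 adjusted over the list alone, camera adjusted p = 4.00e-11), and Ly6d (1 to 31929 UMIs) and Calm4 (12.96 ± 0.44) rose. Hrnr, Flg and Sprr2h, at 0 counts in DIV11, were at least 715-fold, at least 259-fold and at least 249-fold higher. Otic epithelium genes fell in them (0 rose, 10 fell, 1 did not pass, camera adjusted p = 1.17e-09), with Pex5l (-7.07 ± 0.36), Fgf8 (-7.02 ± 0.41), Cldn9 (-5.45 ± 0.29) and Sorbs2 (-5.37 ± 0.27) lower. The cluster holding the class differs between these days. Fbxo2 fell by 1.65 ± 0.28 here, and rose with classes from resolution 0.5 (1.88) and from resolution 2.0 (2.06). From DIV16 to DIV21 Krt73 (8.32 ± 0.87), Ly6a (7.32 ± 0.31), Mmp3 (6.37 ± 0.58), Wfdc18 (5.88 ± 0.38) and Il24 (5.32 ± 0.90) rose and Gpx3 (3596 to 1 UMIs), Krt77 (-8.51 ± 0.53), Tesc (1461 to 1 UMIs), Krt1 (-6.86 ± 0.61) and Capns2 (-5.28 ± 0.43) fell within them. Hair cell genes were called up (3 rose, 0 fell, 5 did not pass, 4 and 0 adjusted over the list alone, camera adjusted p = 0.0105) with a median log2 fold change of 0.75 and a mean of -0.01. In this class edgeR called 7332 genes in the first step, 4464 without DIV11 replicate 1 and 4373 without DIV11 replicate 2. In the second it called 2256, 894 without DIV16 replicate 2 and 3545 with no filter on low counts.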

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

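The difference in response between hair cell-like and otic epithelium-like cells was tested for the genes named in both classes, and the tests of explanations for the other patterns were chosen only after the results were seen.

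Oc90 and Fbxo2 changed differently between DIV16 and DIV21 in the sensory and the surrounding otic cells. Oc90 fell by 4.34 on the log2 scale within hair cell-like cells and changed by 0.20 within otic epithelium-like cells, a difference of -4.59 ± 0.47 (edgeR interaction term, adjusted p = 0.000938). Fbxo2 rose by 1.30 within otic epithelium-like cells (adjusted p = 0.00274) and did not pass within hair cell-like cells (0.42, adjusted p = 0.0762; called without DIV21 replicate 1 or DIV21 replicate 2, at 0.00252 and 0.011), a difference of -0.95 ± 0.16 (adjusted p = 0.0109). The test covered 12129 genes, called 536 and left 2 residual degrees of freedom, and of the 6 genes named in both classes the other 4 did not pass, which were Lcn2 (1.91, adjusted p = 0.865), Sox2 (0.30, adjusted p = 0.504), Pou4f3 (-0.99, adjusted p = 0.721) and Pax2 (0.85, adjusted p = 0.115). Lists of neighbouring cells, such as otic supporting cell (camera adjusted p = 0.00107), also fell in hair cell-like cells, none passing with an estimated correlation. Whether a lower share of RNA from such neighbouring cells explains the fall of Oc90 was not tested.

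Barcodes with at least 20% mitochondrial UMIs, which were filtered out before the comparisons of the report, made up a mean of 45.9% of the barcodes at DIV4, against 2.99% at DIV3, 1.77% at DIV8, 0.915% at DIV11, 1.27% at DIV16 and 0.876% at DIV21. Both DIV4 libraries show it (51.1% and 40.6%), so the loss of barcodes goes with the day, and handling and biology of that day were not separated. Only 438 and 944 of these barcodes had at least 500 genes, so most of them would also have failed the gene limit. Under 500 genes were found in 54.7% and 49.4% of all DIV4 barcodes. With all deposited barcodes in place of the filtered ones, 5433 genes were called between DIV3 and DIV4 in place of 5519.

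Acute-phase genes rose from DIV16 to DIV21, Lcn2, Saa3, C3 and Hp in mesenchyme-like cells, Lcn2 and Hp in otic epithelium-like cells and Lcn2 in hair cell-like cells. Free RNA from a single source would hold these genes in the same ratio in every class, but the SD over the 4 genes of the log2 ratio between mesenchyme-like and otic epithelium-like cells was 3.60, which argues against it for the 4 genes together (1.01 against muscle-like cells, with 1.18 and 0.911 in the single libraries). For Saa3 and C3 alone free RNA from mesenchyme-like cells is not excluded, since at DIV21 these stood at 806 and 132 CPM there and at 6.01 to 10.7 and 2.09 to 10.7 CPM in hair cell-like, otic epithelium-like, muscle-like and epidermis-like cells and cluster 33. Unnamed cluster 33, which carries Lcn2 and Sftpc, is not a candidate source for mesenchyme-like cells on its own, since their ratio to that cluster lay 12.61 log2 units above that of Sftpc in the median of the 4 genes. A response to culture age may explain the rise, and it stays open because age and day cannot be separated in this design.

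The dissociation response list, which holds Fos and Junb, was called up by camera from DIV4 to DIV8, from DIV8 to DIV11 and from DIV11 to DIV16, with 13, 9 and 14 of its 14 genes rising, but did not pass with an estimated correlation (adjusted p = 0.134, 0.225 and 0.149). The thermolysin step as the whole cause is argued against by DIV8 and DIV16, which share it and differ by a median of 3.97 log2 units over the 14 genes (range 1.47 to 6.17). A change in the share of classes as the whole cause is argued against by mesenchyme-like cells alone, in which the median over the 14 genes was 3.16 from DIV11 to DIV16 (13 rose and 1 did not pass), although the clusters holding this class differ between these days. From DIV16 to DIV21 the list was called up within otic epithelium-like (camera adjusted p = 1.78e-09) and mesenchyme-like cells (3.15e-05) and down within hair cell-like (0.0132) and epidermis-like cells (0.0421), none passing with an estimated correlation (adjusted p = 0.352 to 0.766). Differences in dissociation between the days and a response of the older tissue may both contribute, and the libraries hold no value that separates them.

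Keratinocyte genes were counted in other classes at DIV16, with at least 1 epidermis list UMI in 43.5% and 48.8% of mesenchyme-like cells. Krt10, 4658 of these UMIs, went from 47.9 to 32.8 CPM by DIV21, against 3170 to 194 in epidermis-like cells. Krt10 thus did not track that class as Krt1 did (7.44 to 0.116 against 1610 to 12.2). Over the list free RNA and doublets cannot be told apart from expression. Over 10 genes the SD of the log2 ratio of mesenchyme-like to muscle-like cells was 1.06 (0.947 and 1.51 in the single libraries). Absence of free RNA asked for more than 1 in both. The 2% of mesenchyme-like cells with most list UMIs held 22.8% of them, between the bounds for doublets and for their absence. By library the SD was 1.86 and 1.38 against otic epithelium-like (8 genes) and 1.01 and 1.63 against hair cell-like cells (4 genes), above that bound. Against epidermis-like cells it was 0.779 and 0.618, below the bound. The bound was changed after the value was seen, so this test carries little weight.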

How the results depend on the processing

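The automatic doublet threshold, the fits without the DIV3 and DIV4 libraries and the within-class tests with classes at other resolutions were chosen only after the results were seen; the other alternatives were planned.

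Directions of called values held widely and counts of called genes moved with the number of samples and with depth. Of 6859 values of named genes under alternatives, 6670 kept their side of the threshold, 154 lost the call, 31 gained it and 4 reversed. A called value that kept its side also kept its direction, while a change of direction that passed in neither fit counts as kept. Of 490 list values 408 kept and 82 lost the call, and of 662 share values 579 kept, 75 lost, 7 gained and 1 reversed. Counts stayed within 1.5-fold in 141 of 176 values.

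Leaving out a library in turn gave 2659 to 6095 called genes for DIV4 against DIV3, 6266 to 8071 for DIV8 against DIV4, 3694 to 4294 for DIV11 against DIV8, 6649 to 7368 for DIV16 against DIV11 and 1965 to 3603 for DIV21 against DIV16. Within classes it gave 656 to 2123 in otic epithelium-like and 517 to 1741 in hair cell-like cells, 7857 to 8531 and 2898 to 6452 in mesenchyme-like and 4373 to 6153 and 894 to 1768 in epidermis-like cells. Called lists ranged from 68 to 81 (70 with all libraries) and called class shares from 21 to 25 (24 with all). A lone library left in a day is assumed to vary like those of the other days, and leaving out a library lowers the minimum of filterByExpr, so that more genes are tested. Without DIV3 replicate 1, the median log2 fold change of all genes between DIV3 and DIV4 moved to -0.16.

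Thinning to the smallest library left 14512 genes and gave 3230, 6124, 3343, 5557 and 1873 called genes in order of day, where the lower depth by construction leaves fewer calls. DESeq2 called 1329 genes in otic epithelium-like and 358 in hair cell-like cells, and no low-count filter 3545 in epidermis-like cells at DIV21; the cause was not tested. With an estimated correlation 11 lists were called, and fry, which asks whether the genes of a list move one way and compares with no other genes, called 123. Limma on log2 shares called 8 changes of class shares, which by construction gives small counts no separate counting error; the cause was not tested further.

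A replicate block gave 3399 called genes in otic epithelium-like and 567 in hair cell-like cells and otherwise counts within 1.5-fold. The numbers do not pair the samples: over 15 pairs of days the correlation of the differences between replicates 1 and 2 ran from -0.0891 to 0.1086, with 1 over 0.1.

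Reversed values were Pax2 from DIV4 to DIV8 without DIV8 replicate 1 (-2.19), Myo7a from DIV8 to DIV11 with libraries thinned to the same UMI total (1.44), and Fbxo2 within epidermis-like cells from DIV11 to DIV16 with classes at resolution 0.5 (1.88) and 2.0 (2.06). For Fbxo2 these classes leave out most of the DIV11 cells of cluster 30 of the resolution 2.0 clustering, which carry otic genes. The otic epithelium-like share from DIV11 to DIV16 reversed at resolution 0.5 (-0.76), where the class takes in 355 and 264 DIV11 cells that lie in the epidermis-like class at resolution 1.0. For Pax2 and Myo7a the cause was not tested.

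Among class shares, a limit of 1000 genes per cell ended 8 calls, leaving out libraries 31 and limma 31, counting unnamed clusters. Within-class results for otic epithelium-like cells between DIV11 and DIV16 could not be had at resolution 1.0 or 2.0 for lack of DIV11 cells, and the limit of 100 cells per library could not be run for hair cell-like cells. Of simulated 2-fold changes 38% were recovered for DIV8 against DIV4 and 44% in otic epithelium-like cells, so many are missed. Per comparison 4 to 22 unchanged genes were called.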

Other observations

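The values in this part, and the test in it, were chosen after the data were seen. Early otic cells may be hidden in the class called epidermis-like at DIV11. At resolution 2.0, cluster 30 (364 and 273 DIV11 cells, of which 354 and 263 lie in that class) carried otic genes. Cluster 24 of the same clustering (458 and 360 cells, 448 and 354 of them in that class) carried keratinocyte genes. Over the 13 genes of the otic epithelium list, the median log2 ratio of cluster 30 to cluster 24 was 3.13 in 1 library and 3.33 in the other, and all 13 were higher in both libraries. Outside that list, Sox2 stood at 132 ± 11.1 against 3.83 ± 0.872 CPM, Fgf8 at 160 ± 56.0 against 8.22 ± 1.57, Aldh1a3 at 173 ± 64.8 against 3.13 ± 0.442 and Eya1 at 91.5 ± 3.54 against 6.37 ± 1.05. Krt5 stood at 92.8 ± 42.5 against 527 ± 64.9 CPM and Trp63 at 50.3 ± 11.1 against 210 ± 11.0. The naming rule calls cluster 30 non-neural ectoderm-like (score 1.96, with epidermis second at 1.65), so an otic placode or vesicle stage next to epidermal precursors stays a hypothesis, found and tested on the same cells.

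At resolution 0.5, 356 and 267 of the DIV11 cells of cluster 30 lie in the otic epithelium-like class, which then holds 526 and 424 DIV11 and 340 and 283 DIV16 cells and can be compared between these days. Of 12704 genes edgeR called 3310, 1956 higher and 1354 lower at DIV16. Fbxo2 rose by 4.18 on the log2 scale (adjusted p = 6.86e-06), Oc90 by 6.03 (adjusted p = 6.86e-06), Agr3 by 5.40 (adjusted p = 1.23e-05), Tecta by 6.88 (adjusted p = 0.000185) and Lmx1a by 4.21 (adjusted p = 0.000293). Fgf8 fell by 4.19 (adjusted p = 0.000178), Pax8 by 2.10 (adjusted p = 0.0218), Prox1 by 1.96 (adjusted p = 0.000913) and Top2a by 1.24 (adjusted p = 0.00161), and Dkk4 went from 231 ± 115 CPM to 0 counts.

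Marker genes of vestibular and cochlear hair cells were read in the hair cell-like class at DIV21. Anxa4 stood at 825 ± 2.88 CPM, Calb2 at 666 ± 37.4, Spp1 at 383 ± 239 and Ocm at 249 ± 260, the last with an SD above its mean. Of the other genes of the vestibular list Meis2 stood at 172 ± 12, Agr3 at 63.9 ± 4.35 and Aldh1a3 at 51.2 ± 8.15, below their levels in otic epithelium-like cells (319 ± 81.3, 1420 ± 38.8 and 207 ± 36.4). Cyp26b1 stood at 11.6 ± 8.42, Zbbx at 9.55 ± 6.63 and Mapt at 4.58 ± 4.18. Neither the vestibular nor the cochlear list was called between DIV16 and DIV21 (camera adjusted p = 0.677 and 0.668). Slc26a5, the outer hair cell motor gene, had 0 counts at DIV16 and DIV21, while of the cochlear list Fgf8 stood at 143 ± 20.7 CPM at DIV21, Ikzf2 at 13.6 ± 2.61 and Neurod6 at 7.35 ± 5.66, and Fgf20, Gata3 and Rorb had 3 UMIs each. Insm1 went from 40.4 ± 6.38 CPM at DIV16 to 5.80 ± 2.46 at DIV21 and Slc17a8 from 20.7 ± 2.55 to 89.0 ± 32.9.

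Some unnamed clusters carry genes of recognisable tissues, read as levels over all their cells. Cluster 33 (664 cells) held Wfdc18 at 3140 CPM, Lcn2 at 674 and Sftpc at 604, a lung surfactant gene. Cluster 14 (78 cells) held Rhox6 at 2330 CPM, Rhox9 at 1770 and Ctsj at 463, genes of trophoblast. Cluster 24 (1589 cells) held Ptgds at 9570 CPM, Slc6a13 at 272 and Otor at 196, genes of fibroblasts around the ear and brain, and cluster 16 (1029 cells) held Fabp7 at 2720, a gene of glia.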
